A study of Mus musculus with 12 samples.

How the data were processed

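The series measures transcripts in follicular B cells sorted from mouse spleen, from wild-type (WT) mice and from mice with the IkL/L alleles of Ikzf1. There were 2 genotypes and 3 conditions (3 h without stimulus, 3 h with anti-IgM and 12 h with anti-IgM), so 6 groups of 2 arrays and 12 arrays in all. Per the labels' protocols, 100 ng of total RNA was labelled in 2 cycles and hybridized to an Affymetrix mouse 3' expression array. The deposited values are log2 signals summarized with RMA, per the submitters' processing notes, which give no version. Groups and replicate numbers were read from the sample titles.

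Of 45037 probe sets, 34945 carry 1 gene symbol, 932 carry several and 9160 are not listed in the annotation used. Probe sets without a single symbol were left out of the comparisons and are counted in the closing section. Each gene was represented by its probe set with the highest mean over all arrays, which gave 18193 genes, of which 9010 had more than 1 probe set. Array medians between 3.12 and 3.21 lie near the floor of the signal, so many genes are close to background, and the number of arrays limits the precision.

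All 12 arrays were fitted with 1 mean per group in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation (6 residual degrees of freedom, 3.95 prior degrees of freedom). There were 12 comparisons: 3 h and 12 h against unstimulated cells and 12 h against 3 h in each genotype, IkL/L against WT in each condition and on average, and the difference between the genotypes' responses at 3 h and at 12 h. P values were adjusted over all genes of a comparison with the Benjamini-Hochberg method, and a gene counts as changed at an adjusted p under 0.05. SE is the moderated standard error of the log2 difference. The deposited values hold no background call, so after the values were seen a floor was set at 4.21, 1 above the highest array median. Where an array of the lower group is under it, the fold is given as "at least", from the higher group's mean over the lower group's with such arrays raised to the floor. The log2 difference, SE and p beside it, the order of genes in the rule below and log2 values printed alone (as for Icosl, Ifit1bl1, Pecam1, Pirb, Spry2 and Ell2) are from the values as deposited. A floor of 4.58, 1 above the highest median over genes, would lower the bound of S1pr3 in WT at 3 h from 18.4 to 14.2.

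Gene lists were tested with camera at a preset correlation of 0.01, adjusted within a comparison over the 30 lists with at least 5 measured genes, of 31 lists written down from general knowledge. The same lists were tested with camera with an estimated correlation and with fry. Fry results are printed for a part of the lists. They cover the activation, signalling, cell cycle and metabolic groups named in the report, and the B cell subset, BCL2 family, Notch, Ikaros family and other-cell-type markers given at the end. The groups, comparisons, threshold, list tests and first set of other settings were chosen before the data were examined.

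Genes are named by a rule. In each comparison the rule takes the 8 largest rises and 8 largest falls among genes past the threshold whose groups do not overlap (5 and 5 for 12 h against 3 h), leaving out clone and locus names. It adds up to 3 members of each list with the largest changes past the threshold, and, for every comparison, Ikzf1, Ikzf3, Myc, Egr1, Cd69, Cd86, Ccnd2, Cdkn1b, Fcgr2b and Cd22. The text prints a part of these, the largest first, and any gene outside the rule is said to be chosen after its values were seen.

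The series reports 2 independent experiments, so it was checked whether arrays with the same replicate number deviate together. Over the 6064 brightest genes, the deviations of same-numbered arrays correlated with r between 0.546 and 0.619 within WT and between 0.354 and 0.49 within IkL/L, and between 0.026 and 0.31 across genotypes. Sex-linked transcripts also set the 3 WT replicate 1 arrays apart. Within a genotype every pair of groups was over 0.1, while across genotypes 8 of 9 were. The numbers were therefore taken to pair arrays within a genotype, and a block for replicate within genotype was fitted beside the unblocked model. Pairing across genotypes is left open: Mid1 was higher in replicate 1 and S100a8 in replicate 2 in all 6 groups, but the sex-linked transcripts part only the WT replicates. The interferon genes, higher in replicate 1 in WT, were higher in replicate 2 in unstimulated IkL/L cells (medians 6.55 and 5.55). In stimulated IkL/L cells they were somewhat higher in replicate 1 (6.04 and 5.67 at 3 h, 5.67 and 5.32 at 12 h). The counts with a replicate term shared by both genotypes are in the closing section.

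Other settings fixed in advance were a replicate term shared by both genotypes, the mean of all probe sets of a gene, every probe set on its own, removal of the dimmest 1 in 3 genes, an intensity trend, array weights, only the arrays compared, median centring, scaling to equal housekeeping means and each array left out in turn. Chosen after the data were seen were the block within genotype, with camera at the preset and at an estimated correlation, the source as a random block, 1 mean per source, and fits without WT replicate 1 or without IkL/L replicate 2 in all conditions. Where a fit leaves 1 array in a group, that array is assumed to vary like the other groups. The model was tested on simulated data with 50 genes changed at each of 4 sizes. For the 3 h WT response it recovered 10% of the changes of log2 0.5, 70% of those of log2 1.0 and 100% of those of log2 2.0, with 4 false calls. For the difference between responses at 3 h it recovered 2%, 34% and 94%, with 2 false calls. The simulated arrays varied independently, without the likeness of same-numbered arrays found in the data. A far smaller share of genes was changed than the 19.4% called in WT cells at 3 h. Recovery and false calls in the real data may therefore differ.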

Results

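Transcript levels were measured in follicular B cells sorted from the spleens of 6-week-old mice, either wild type (WT) or carrying the IkL/L alleles, which leave the cells short of the transcription factor Ikaros. Follicular cells are the main recirculating B cells of the spleen and were sorted as B220-positive cells with high CD23 and low CD21, at a purity above 98%. The cells were cultured for 3 h without stimulus, or for 3 h or 12 h with 10 µg/ml of goat F(ab')2 fragments against IgM, which cross-link the B cell receptor (BCR). Each of the 6 groups held 2 arrays, so n = 2 per group throughout, and 12 arrays were compared over 18193 genes. Array medians lay between 3.12 and 3.21 on the log2 scale, and the replicates of a group correlated across genes with r from 0.99 to 0.994. Folds marked "at least" are bounds for genes whose lower group lies near the signal floor, set at 4.21. The series describes 2 independent experiments. Sex-linked transcripts, given further on, show that the 2 WT replicates came from different mice, while these transcripts do not part the IkL/L replicates. Mid1 (7.79 and 5.26) and Jchain (5.64 and 8.68), chosen after their values were seen, differ between the unstimulated IkL/L replicates, which does not show that the mice differed. The p values measure the spread between these samples. The 12 h cultures differ from the unstimulated ones in time in culture as well as in stimulation.

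Ikzf1, the gene that the IkL/L alleles alter, had log2 signals of 9.85 and 9.83 in unstimulated WT cells and of 10.00 and 9.94 in unstimulated IkL/L cells. At 3 h the values were 8.93 and 9.10 in WT and 8.58 and 8.08 in IkL/L. At 12 h they were 10.33 and 10.00 in WT and 9.59 and 8.98 in IkL/L. The genotypes did not differ past the threshold in any condition: the log2 difference was 0.13 without stimulus (adjusted p = 0.937), -0.68 at 3 h (adjusted p = 0.193) and -0.88 at 12 h (adjusted p = 0.148). On average over the conditions the difference was -0.48 (adjusted p = 0.0533). Where this probe set lies relative to the change in the allele is not given in the sources used here, so these values check nothing about the genotype. Within IkL/L cells Ikzf1 fell 3.12-fold at 3 h (log2 -1.64, SE 0.22, adjusted p = 0.000413). Its fall in WT cells at 3 h (log2 -0.83, adjusted p = 0.0218) lost its call when any of the 4 WT arrays compared was left out. The adjusted p was then 0.099 without unstimulated replicate 1, 0.0964 without unstimulated replicate 2, 0.128 without 3 h replicate 1 and 0.0594 without 3 h replicate 2, and 0.294 without WT replicate 1 in all conditions.

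The first question was how WT cells answer to BCR cross-linking. After 3 h, S1pr3, a receptor for sphingosine-1-phosphate, rose at least 18.4-fold (log2 5.00, SE 0.24, adjusted p = 4.61e-06), Fabp5, a fatty acid binding protein, rose 20.4-fold (log2 4.35, SE 0.24) and the peptide transporter Slc15a3 rose 15.1-fold (log2 3.91, SE 0.21). Neurl3, a ubiquitin ligase, fell 26.3-fold (log2 -4.72, SE 0.23, adjusted p = 4.61e-06), the complement regulator Cd55 fell 19.3-fold (log2 -4.27, SE 0.22) and Pgap1 fell at least 8.27-fold (log2 -4.12, SE 0.15). Myc, a driver of growth and proliferation, rose 6.91-fold (log2 2.79, SE 0.25, adjusted p = 5.4e-05). The cell cycle inhibitor Cdkn1b fell 4.73-fold, the inhibitory receptor Fcgr2b 4.37-fold and the inhibitory receptor Cd22 3.51-fold.

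Genes for growth rose together in WT cells at 3 h. All 30 measured ribosome biogenesis genes rose (30 adjusted over the list alone), led by Rrp12 (log2 2.24), Nop16 (log2 2.21) and Nolc1 (log2 2.14). The camera test gave an adjusted p of 4.45e-26, and adjusted p = 0.0881 with an estimated correlation. Of 20 genes of amino acid transport and one-carbon metabolism, 16 rose and 0 fell (17 and 0 adjusted over the list alone), with Shmt1 at log2 2.87 and Asns, which makes asparagine, at log2 1.91. Its camera adjusted p was 6.07e-12, and adjusted p = 0.19 with an estimated correlation. Of 16 cholesterol synthesis genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone), with Cyp51 at log2 2.05 and Sqle at log2 2.02 (camera adjusted p = 4.72e-08, and adjusted p = 0.0881 with an estimated correlation). In glycolysis and glucose uptake 5 of 17 rose and 2 fell (5 and 2 adjusted over the list alone), with hexokinase Hk2 at log2 2.69. That list had a camera adjusted p of 0.0151, and adjusted p = 0.146 with an estimated correlation. With fry the adjusted p was 8.97e-05 for ribosome biogenesis and 0.00113 for amino acid and one-carbon genes. It was 0.000137 for cholesterol synthesis and 8.05e-05 for glycolysis.

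Some activation genes rose and most quiescence genes fell in the same WT cells. Of 24 immediate early genes 9 rose and 3 fell (11 and 3 adjusted over the list alone), led by Fosl2 (log2 3.42), Maff (log2 3.33) and Nr4a3 (log2 2.97), with camera adjusted p = 0.00152 and adjusted p = 0.477 with an estimated correlation. Of 19 NF-kB targets 11 rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.000307, and adjusted p = 0.37 with an estimated correlation), although the largest change was the fall of Bcl3 (log2 -2.61). Of 20 activation and costimulation surface proteins 9 rose and 2 fell (9 and 2 adjusted over the list alone), with Icosl, the ligand of ICOS, at log2 -3.34 and Il2ra, the IL-2 receptor alpha chain, at log2 2.60 (camera adjusted p = 0.0119, and adjusted p = 0.411 with an estimated correlation). Of 13 MAPK feedback regulators 4 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0151, and adjusted p = 0.243 with an estimated correlation). Of 23 genes of quiescence and FOXO activity 2 rose and 15 fell (2 and 16 adjusted over the list alone; camera adjusted p = 1.5e-08, and adjusted p = 0.0881 with an estimated correlation), among them Rbl2 (log2 -2.88) and Klf3 (log2 -2.73).

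Many parts of the receptor's own signalling machinery were lower in stimulated WT cells. Of 28 BCR signalling components 14 fell and 4 rose at 3 h (17 and 5 adjusted over the list alone). Syk, the kinase that binds the activated receptor, fell 8.94-fold (log2 -3.16, SE 0.28, adjusted p = 5.26e-05), Dapp1 at least 5.79-fold and Bank1 4.97-fold. Camera gave an adjusted p of 0.000295 for this list, and adjusted p = 0.282 with an estimated correlation. Of 25 inhibitory regulators of BCR signalling 12 fell and 5 rose (12 and 5 adjusted over the list alone), led by Rgs1, which rose (log2 3.77), and Siglecg, which fell (log2 -2.53). That list's camera adjusted p was 0.0149, and 0.118 under housekeeping scaling; adjusted p = 0.146 with an estimated correlation.

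In limma, 3529 genes changed in WT cells at 3 h, 1665 up and 1864 down, and of these 850 rose and 980 fell at least 2-fold. Scaling the arrays to equal means of 11 housekeeping genes, some of which rose themselves (Tfrc log2 1.52), lowered the share of changed genes that were higher from 47.2% to 33.5%. The same scaling shifted the median of all genes by -0.158 at 3 h in WT and -0.287 at 12 h in WT, and in IkL/L by -0.161 at 3 h and -0.429 at 12 h. Changes are therefore relative to an equal overall signal. Leaving out the female WT source described further on (WT replicate 1 in all 3 conditions) left 1771 genes at 3 h and 1639 at 12 h.

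**Figure D1:**
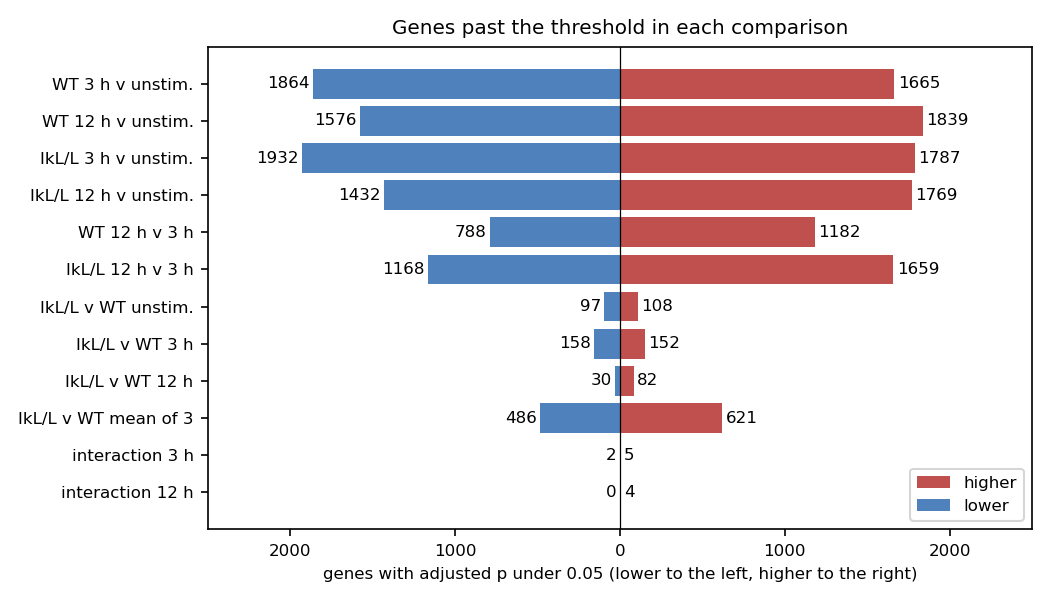
Bars show the number of genes with an adjusted p under 0.05 in limma in each of 12 comparisons (horizontal axis, genes; higher to the right in red, lower to the left in blue; 2 arrays per group). Between 3201 and 3719 genes differed between stimulated and unstimulated cells, the 12 h groups differing also in time in culture. Between 112 and 310 genes differed between IkL/L and WT within a condition.

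After 12 h in WT cells Tacc2, a centrosome-associated protein, was at least 15.5-fold higher than in unstimulated cells (log2 4.91, SE 0.34, adjusted p = 1.37e-05), Havcr1, also called TIM-1, was at least 15.3-fold higher (log2 4.18, SE 0.28) and Niban1 at least 7.46-fold higher (log2 3.82, SE 0.54). Neurl3 was 42-fold lower (log2 -5.39, SE 0.23, adjusted p = 1.67e-06). Ifit1bl1, an interferon-inducible gene, fell by 5.04 on the log2 scale (SE 1.19, adjusted p = 0.0132), but not past the threshold without unstimulated replicate 1 (adjusted p = 0.107), without 12 h replicate 2 (adjusted p = 0.0952) or without the IkL/L replicate 2 arrays (adjusted p = 0.0527). Rasa3, which restrains Ras signalling, was 28.5-fold lower (log2 -4.83, SE 0.22), and the cholesterol exporter Abca1 was 25.4-fold lower (log2 -4.67, SE 0.20). S1pr1, the receptor that lets lymphocytes leave lymphoid organs, was at least 11.8-fold lower (log2 -3.60, SE 0.18). Myc was still 2.34-fold higher (log2 1.23, adjusted p = 0.00626), a call lost without unstimulated replicate 2 (adjusted p = 0.053) and without WT replicate 1 in all conditions (adjusted p = 0.108).

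Several gene groups kept their 3 h direction in WT cells at 12 h. Of the 16 cholesterol synthesis genes 15 were higher (16 adjusted over the list alone), led by Cyp51 (log2 2.52) and Lss (log2 2.37), with camera adjusted p = 1.44e-12 and adjusted p = 0.0404 with an estimated correlation. Of 23 quiescence genes 18 were lower and 0 higher (18 and 0 adjusted over the list alone), among them S1pr1, Pik3ip1 (log2 -3.49) and Klf2 (log2 -3.04). Its camera adjusted p was 6.29e-16, and adjusted p = 0.0224 with an estimated correlation. Of 25 inhibitory regulators 13 were lower and 3 higher (13 and 3 adjusted over the list alone; camera adjusted p = 0.000367, and adjusted p = 0.0449 with an estimated correlation), among them the ubiquitin ligase Cblb (log2 -2.29) and Pecam1 (log2 -2.25). Ribosome biogenesis had 27 of 30 higher (30 adjusted over the list alone; camera adjusted p = 2.67e-16, and adjusted p = 0.142 with an estimated correlation). Glycolysis had 10 of 17 higher and 3 lower (10 and 3 adjusted over the list alone; camera adjusted p = 0.00117, and adjusted p = 0.0585 with an estimated correlation).

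Amino acid and one-carbon genes had 11 of 20 higher in WT cells at 12 h and 0 lower (14 and 0 adjusted over the list alone; camera adjusted p = 9.22e-07, and adjusted p = 0.435 with an estimated correlation). BCR signalling components had 12 of 28 lower and 2 higher (13 and 2 adjusted over the list alone; camera adjusted p = 1.1e-05, and adjusted p = 0.224 with an estimated correlation), although Vav3, an exchange factor downstream of the receptor, was 9.55-fold higher. Of 32 genes of G1/S and DNA replication 12 were higher and 3 lower (15 and 4 adjusted over the list alone), led by Rfc4 (log2 2.20) and Uhrf1 (log2 1.74). That list's camera adjusted p of 0.0107 became adjusted p = 0.442 with an estimated correlation, 0.0945 without 12 h replicate 1 and 0.193 without WT replicate 1 in all conditions. In all, 3415 genes changed, 1839 up and 1576 down, and 2237 without unstimulated replicate 2. Under housekeeping scaling the share that was higher went from 53.9% to 23.8%. Type I interferon genes, with 0 of 19 past the threshold in limma, gave a camera adjusted p of 0.125, and 0.000536 with a block for replicate within genotype, in the direction of lower values, a call lost with an estimated correlation in that fit (adjusted p = 0.536).

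IkL/L cells also responded strongly at 3 h. S1pr3 rose at least 17.2-fold (log2 4.62, SE 0.24, adjusted p = 3.24e-06), Rgs1, which limits G protein signalling, 12.4-fold (log2 3.63, SE 0.26) and Bex1 at least 8.13-fold ( log2 3.50, SE 0.42). Neurl3 fell at least 26.8-fold (log2 -5.09, SE 0.23, adjusted p = 2.14e-06), Sting1, an adaptor in the response to cytosolic DNA, 24.8-fold (log2 -4.63, SE 0.33) and Rasa3 23.8-fold (log2 -4.57, SE 0.22). Myc rose 4.45-fold (log2 2.15, SE 0.25, adjusted p = 0.000206), and the costimulatory ligand Cd86 rose 2.76-fold. Syk fell 16.4-fold, the pro-apoptotic Bmf 11.1-fold and the receptor chain Cd79b 10.9-fold. In limma 3719 genes changed, 1787 up and 1932 down, and 48.1% were higher, or 32.6% under housekeeping scaling. Without IkL/L replicate 2 in all conditions the count was 2171.

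The gene groups of IkL/L cells at 3 h moved in these directions. Ribosome biogenesis had 29 of 30 higher (30 adjusted over the list alone; camera adjusted p = 1.92e-25, and adjusted p = 0.0994 with an estimated correlation). Amino acid and one-carbon genes had 16 of 20 higher (16 adjusted over the list alone; camera adjusted p = 2.74e-10, and adjusted p = 0.212 with an estimated correlation). Cholesterol synthesis had 11 of 16 higher and 1 lower (13 and 2 adjusted over the list alone; camera adjusted p = 9.03e-07, and adjusted p = 0.0994 with an estimated correlation). Quiescence genes had 18 of 23 lower and 2 higher (18 and 2 adjusted over the list alone; camera adjusted p = 4.09e-09, and adjusted p = 0.0994 with an estimated correlation). BCR signalling components had 15 of 28 lower and 4 higher (18 and 6 adjusted over the list alone; camera adjusted p = 0.000178, and adjusted p = 0.26 with an estimated correlation). MAPK feedback regulators had 7 of 13 higher (7 adjusted over the list alone), among them Spry2, an inhibitor of Ras and ERK signalling (log2 2.13), with camera adjusted p = 0.000178 and adjusted p = 0.0994 with an estimated correlation. Immediate early genes had 10 of 24 higher and 2 lower (11 and 2 adjusted over the list alone; camera adjusted p = 0.000855, and adjusted p = 0.544 with an estimated correlation), and activation surface proteins 9 of 20 higher and 2 lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.00132, and adjusted p = 0.292 with an estimated correlation).

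After 12 h in IkL/L cells, Nrp1, a semaphorin and VEGF coreceptor, was at least 16.3-fold higher than in unstimulated IkL/L cells (log2 4.83, SE 0.47, adjusted p = 0.000106), Tacc2 at least 15.4-fold (log2 4.55, SE 0.34) and the cystathionine lyase Cth at least 12.8-fold (log2 4.45, SE 0.54). The inhibitory receptor gene Pdcd1 was at least 13-fold higher (log2 4.42, SE 0.25), and the receptor tyrosine kinase Axl at least 7.59-fold higher (log2 4.02, SE 0.16, adjusted p = 1.23e-06). Neurl3 was at least 26.8-fold lower (log2 -5.69), Abca1 50.9-fold lower (log2 -5.67) and Rasa3 25.8-fold lower (log2 -4.69). The chemokine Ccl22 was at least 5.56-fold higher (log2 2.95, SE 0.15, adjusted p = 4.59e-06). In limma 3201 genes changed, 1769 up and 1432 down. The count was 1905 without 12 h replicate 2 and 1381 without IkL/L replicate 2 in all conditions. Under housekeeping scaling 816 genes were higher and 9145 lower, so the share that was higher went from 55.3% to 8.19%. The scaling genes moved themselves in this comparison, with 4 of 11 higher and 0 lower (4 and 0 adjusted over the list alone). Camera gave an adjusted p of 0.0256 for them, and adjusted p = 0.192 with an estimated correlation.

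Cholesterol synthesis had 14 of 16 genes higher in IkL/L cells at 12 h (15 adjusted over the list alone), led by Cyp51 at 15.4-fold, with Lss at log2 2.97 and Idi1 at log2 2.92 (camera adjusted p = 3.46e-16, and adjusted p = 0.0202 with an estimated correlation). Glycolysis had 9 of 17 higher and 0 lower (10 and 0 adjusted over the list alone), with pyruvate kinase Pkm at log2 1.79 (camera adjusted p = 6.24e-05, and adjusted p = 0.033 with an estimated correlation). Quiescence genes had 18 of 23 lower and 0 higher (20 and 1 adjusted over the list alone; camera adjusted p = 3.46e-16, and adjusted p = 0.0202 with an estimated correlation). G1/S and DNA replication had 15 of 32 higher and 2 lower (17 and 3 adjusted over the list alone; camera adjusted p = 0.000436, and adjusted p = 0.192 with an estimated correlation). BCR signalling components had 15 of 28 lower and 1 higher (15 and 3 adjusted over the list alone; camera adjusted p = 1.12e-05, and adjusted p = 0.192 with an estimated correlation). Across the 4 comparisons with unstimulated cells, the camera calls that held with an estimated correlation were cholesterol synthesis and quiescence at 12 h in both genotypes, inhibitory regulators at 12 h in WT and glycolysis at 12 h in IkL/L; none of the other 8 comparisons had a list that held. With an estimated correlation and the block for replicate within genotype, only quiescence at 12 h held (adjusted p = 0.0253 in WT and 0.0232 in IkL/L). In that fit cholesterol synthesis had adjusted p = 0.134 in WT and 0.0877 in IkL/L, inhibitory regulators in WT 0.145 and glycolysis in IkL/L 0.101. With fry, without that block, the lists called by camera in the 4 comparisons with unstimulated cells were called too, with exceptions in IkL/L only. These were NF-kB targets at 3 h (fry adjusted p = 0.0732) and immediate early genes at 12 h (0.128).

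Between 3 h and 12 h of stimulation, many early genes receded, and cholesterol synthesis genes rose further, most of them in IkL/L. In WT cells Gng4, a G protein subunit, was 13.2-fold lower at 12 h than at 3 h (log2 -3.73, SE 0.44, adjusted p = 0.000714) and Pdcd1 was at least 5.86-fold higher (log2 3.46, SE 0.25, adjusted p = 6.9e-05). In IkL/L cells Gng4 was 24.5-fold lower (log2 -4.62, SE 0.44), the orphan nuclear receptor Nr4a2 18.6-fold lower (log2 -4.22, SE 0.35) and catalase, Cat, at least 6.9-fold higher (log2 3.73, SE 0.32). Of 24 immediate early genes 10 were lower and 1 higher in WT (11 and 1 adjusted over the list alone; camera adjusted p = 1.72e-07, and adjusted p = 0.306 with an estimated correlation), and 12 were lower and 2 higher in IkL/L (15 and 2 adjusted over the list alone; camera adjusted p = 4.8e-09, and adjusted p = 0.278 with an estimated correlation). Activation surface proteins were lower for 11 of 20 and higher for 1 in both genotypes, including Cd86 (log2 -2.25 in WT and -1.62 in IkL/L), with camera adjusted p = 5.14e-07 in WT and 4.32e-06 in IkL/L (11 and 1 adjusted over the list alone in each; adjusted p = 0.306 and 0.278 with an estimated correlation). NF-kB targets were lower for 7 of 19 in WT (9 adjusted over the list alone; camera adjusted p = 5.96e-07, and adjusted p = 0.306 with an estimated correlation) and for 7 of 19 in IkL/L, where 1 was higher (10 and 2 adjusted over the list alone; camera adjusted p = 1.07e-06, and adjusted p = 0.278 with an estimated correlation).

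Metabolic and growth genes went different ways between 3 h and 12 h. Ribosome biogenesis genes were lower for 9 of 30 in WT and higher for 0 (15 and 0 adjusted over the list alone; camera adjusted p = 6.62e-11, and adjusted p = 0.306 with an estimated correlation), and lower for 11 and higher for 0 in IkL/L (17 and 0 adjusted over the list alone; camera adjusted p = 5.8e-10, and adjusted p = 0.278 with an estimated correlation). Cholesterol synthesis had 12 of 16 higher in IkL/L (13 adjusted over the list alone; camera adjusted p = 6.54e-08, and adjusted p = 0.138 with an estimated correlation) and 5 of 16 higher in WT (6 adjusted over the list alone; camera adjusted p = 0.00358, adjusted p = 0.306 with an estimated correlation, and 0.104 without WT 3 h replicate 2). Amino acid and one-carbon genes had 4 of 20 lower and 2 higher in both genotypes (5 and 2 adjusted over the list alone in WT, 4 and 2 in IkL/L), with camera adjusted p = 0.0108 in WT and 0.0343 in IkL/L, and adjusted p = 0.614 and 0.752 with an estimated correlation. That call was lost with fry (0.211 in WT and 0.255 in IkL/L) and under housekeeping scaling (0.0688 and 0.24). It was also lost in WT without 12 h replicate 1 (0.193) or WT replicate 1 in all conditions (0.252), and in IkL/L without 3 h replicate 2 (0.061) or 12 h replicate 1 (0.551). Glycolysis genes, with 3 of 17 higher and 1 lower in WT and 7 higher and 0 lower in IkL/L (4 and 1, and 9 and 4, adjusted over the list alone), were not called by camera (adjusted p = 0.526 and 0.154) but were called as higher by fry (adjusted p = 0.0239 and 0.000708).

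In WT 1970 genes changed between 3 h and 12 h, 1182 up and 788 down, and 3090 with a block for replicate within genotype. The WT count was 1055 without 3 h replicate 1, 1296 without 3 h replicate 2, 1124 without 12 h replicate 2 and 524 without WT replicate 1 in all conditions. In IkL/L 2827 genes changed, 1659 up and 1168 down. The IkL/L count was 1833 without 3 h replicate 1, 1629 without 3 h replicate 2, 1797 without 12 h replicate 2 and 1058 without IkL/L replicate 2 in all conditions. Under housekeeping scaling 755 genes were higher and 1099 lower in WT, and in IkL/L the share that was higher went from 58.7% to 25.1%. With the block, camera also called lower interferon genes (adjusted p = 0.0138, against 0.425 without it) and lower chemokines and cytokines (adjusted p = 0.0205, against 0.0762) in WT. Both calls were lost with an estimated correlation in the blocked fit (adjusted p = 0.587 and 0.218).

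**Figure D2:**
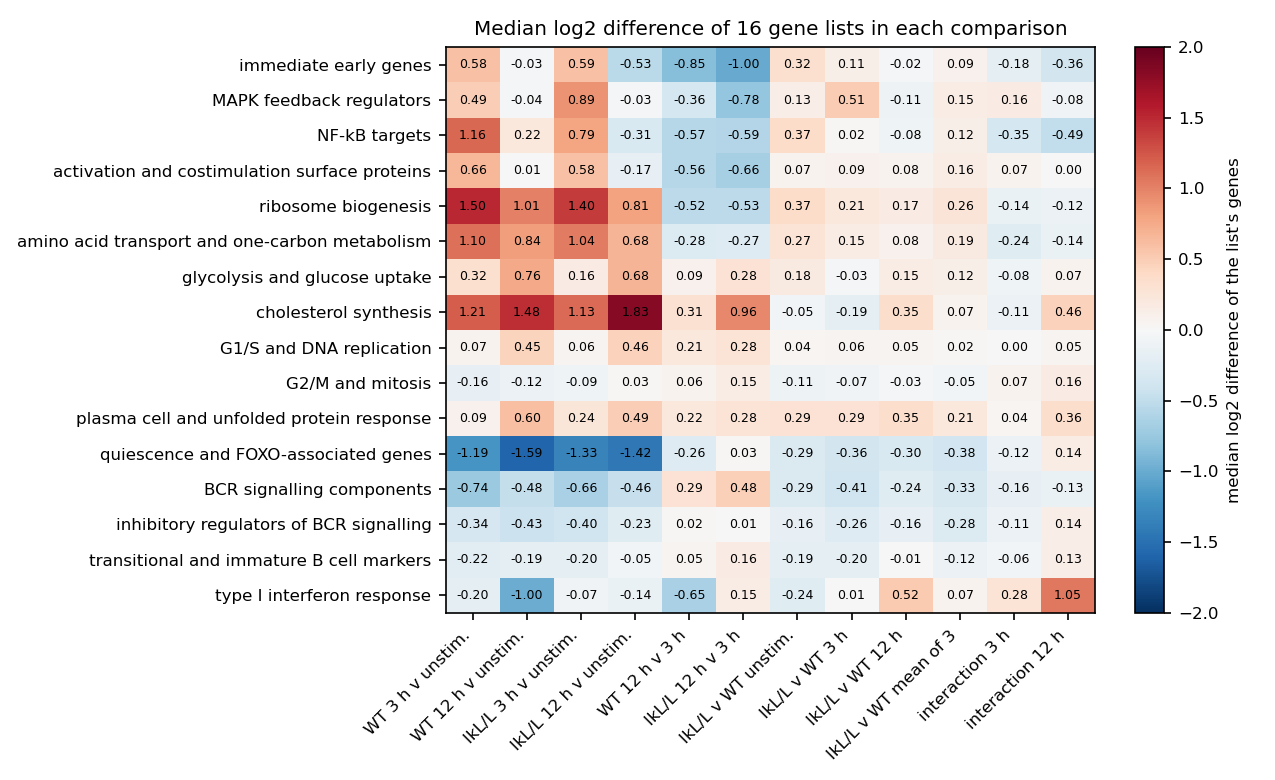
Each cell gives the median log2 difference of the measured genes of 1 of 16 gene lists (rows) in 1 of 12 comparisons (columns), with red for higher and blue for lower on a scale from -2.0 to 2.0. Ribosome biogenesis (1.40 in IkL/L at 3 h), cholesterol synthesis (1.48 and 1.83 at 12 h) and quiescence genes (-1.59 and -1.42 at 12 h) keep these signs under housekeeping scaling, whereas medians nearer 0, such as G1/S at 3 h, change sign under it.

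The response was much the same in both genotypes when compared gene by gene. Across the 18193 genes, which are not independent replicates, the log2 changes in WT and IkL/L correlated with Pearson r = 0.893 and Spearman rho = 0.687 at 3 h, and with r = 0.858 and rho = 0.666 at 12 h. The genotypes share no arrays in these correlations. At 3 h 1371 genes rose in both genotypes where chance overlap would give 164, and 1453 fell in both against 198. At 12 h 1329 rose in both against 179 and 1091 fell in both against 124. The chance level takes every gene as equally likely to be called, although many genes lie close to background. The excess over it is therefore not a measure of how alike the responses were. Alkbh8, chosen after its values were seen, was the 1 gene called in opposite directions at 3 h (log2 -0.52 in WT and 0.73 in IkL/L), and Lat2, chosen in the same way, the 1 gene at 12 h (log2 -1.27 and 0.74). The test of their difference gave adjusted p = 0.185 for Alkbh8 and 0.06 for Lat2, and 0.0167 for Lat2 with a block for replicate within genotype.

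**Figure D3:**
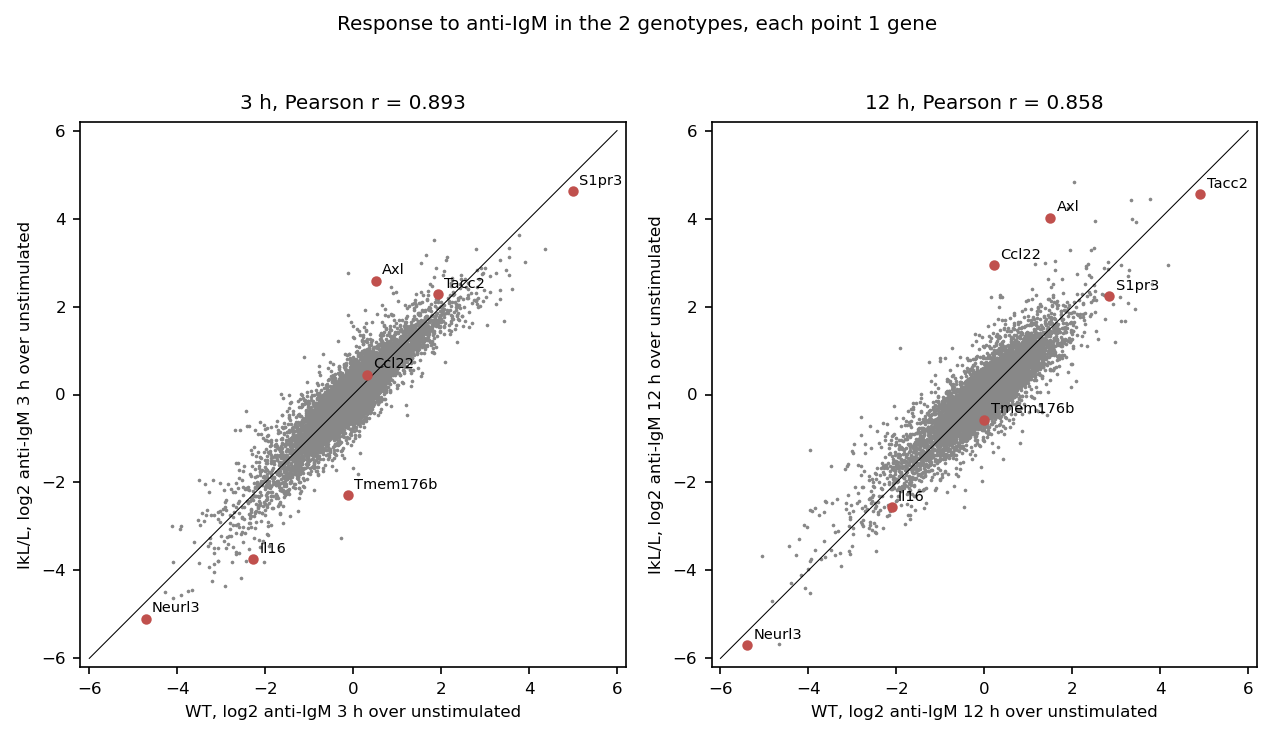
Each point is 1 of 18193 genes, with its log2 change over unstimulated cells in WT on the horizontal axis and in IkL/L on the vertical axis, at 3 h (left) and 12 h (right); each change is the difference of 2 group means of 2 arrays and the line marks equal change. Most genes lie near the line (r = 0.893 and 0.858), while Axl and Ccl22 lie above it at 12 h and Tmem176b below it at 3 h.

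The next question was which genes Ikaros deficiency alters in resting cells. Tmem176b, a membrane protein, was at least 8.09-fold higher in unstimulated IkL/L than in unstimulated WT cells (log2 3.11, SE 0.16, adjusted p = 4.85e-05), the inactive rhomboid protease Rhbdf1 7.42-fold higher (log2 2.89, SE 0.22, adjusted p = 0.00101) and the small GTPase Rasd1 7.09-fold higher (log2 2.83, SE 0.25, adjusted p = 0.00118). These 3 calls held under every setting tried. Sdc1, the plasma cell surface proteoglycan CD138, was at least 4.61-fold lower (log2 -3.13, SE 0.34, adjusted p = 0.00252), though not past the threshold without IkL/L replicate 2 in all conditions (adjusted p = 0.109). Sspn was at least 7.52-fold lower (log2 -3.09, SE 0.54, adjusted p = 0.029), a call lost without WT unstimulated replicate 2 (adjusted p = 0.255), without either unstimulated IkL/L replicate (0.0835 and 0.157) without either 3 h IkL/L replicate (0.0518 each), without IkL/L replicate 2 in all conditions (0.325) and when only the 4 arrays compared were fitted. The ubiquitin ligase Rnf125 was at least 3.26-fold lower (log2 -2.43, SE 0.20, adjusted p = 0.00101) and kept its call under every setting. Bcl2l2, an anti-apoptotic BCL2 family member, was 2.43-fold higher (log2 1.28, adjusted p = 0.00251), but not called without IkL/L replicate 2 in all conditions (adjusted p = 0.0858) or on the mean of its probe sets.

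In unstimulated cells the ribosome biogenesis list was shifted up in IkL/L although 0 of its 30 genes passed in limma (2 adjusted over the list alone), with a median log2 difference of 0.37, a camera adjusted p of 2.18e-08, and adjusted p = 0.339 with an estimated correlation and 0.116 with fry. The same list was shifted up at 3 h (median 0.207, camera adjusted p = 0.000135) and at 12 h (0.165, 0.000809). With an estimated correlation the adjusted p was 0.535 at 3 h and 0.764 at 12 h, and with fry 0.362 and 0.404. On average over the conditions the median was 0.261 (camera adjusted p = 4.55e-09, 0.282 with an estimated correlation and 0.0293 with fry). In unstimulated cells 3 of 23 quiescence genes were lower (7 adjusted over the list alone). Camera gave that list an adjusted p of 1.63e-05, against 0.161 with an estimated correlation and 0.0399 with fry. Of 25 inhibitory regulators of BCR signalling 3 were lower, Lax1, Pirb and Pecam1 (7 adjusted over the list alone). That list had a camera adjusted p of 0.000116, against 0.0827 with an estimated correlation and 0.0121 with fry. Lax1 (log2 -1.50) lost its call without WT unstimulated replicate 2 (adjusted p = 0.0954), and Pecam1 (log2 -1.28) without IkL/L unstimulated replicate 2 (adjusted p = 0.0522). Lax1, Pirb (log2 -1.31) and Pecam1 each lost theirs without IkL/L replicate 2 in all conditions (adjusted p = 0.0748, 0.112 and 0.155), and Lax1 and Pirb without WT replicate 1 in all conditions (0.0859 and 0.0858). NF-kB targets, with 0 of 19 past the threshold in limma (4 higher adjusted over the list alone), had a median of 0.37 and a camera adjusted p of 0.000152, and adjusted p = 0.339 with an estimated correlation. The call was lost with fry (adjusted p = 0.151), without IkL/L unstimulated replicate 2 (0.337) and without IkL/L replicate 2 in all conditions (0.286).

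In unstimulated cells 205 genes differed between genotypes, 108 higher and 97 lower in IkL/L, and 400 with a replicate term shared by both genotypes. The count was 95 without WT unstimulated replicate 1, 33 without WT unstimulated replicate 2, 67 without IkL/L unstimulated replicate 2 and 134 without either 3 h IkL/L replicate. It was 83 without WT replicate 1 and 16 without IkL/L replicate 2 in all conditions. Under housekeeping scaling the share that was higher went from 52.7% to 62.9%.

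At 3 h of stimulation Lif, a cytokine of the IL-6 family, was at least 5.4-fold higher in IkL/L than in WT cells (log2 3.69, SE 0.36, adjusted p = 0.00138) and App, the amyloid precursor protein, at least 6.59-fold higher (log2 2.94, SE 0.25, adjusted p = 0.00087). Bex1 was at least 6.93-fold higher (log2 2.92, SE 0.42, adjusted p = 0.01), but not called without WT 3 h replicate 1 (adjusted p = 0.0562), without IkL/L 3 h replicate 2 (0.115), or without the WT replicate 1 or IkL/L replicate 2 arrays of all conditions (0.103 and 0.0735). The tetraspanin Cd9 was 6.21-fold higher (log2 2.64, SE 0.24, adjusted p = 0.00109). Ms4a6c was 5.5-fold lower (log2 -2.46, SE 0.28, adjusted p = 0.00365), but not called without IkL/L 3 h replicate 2 (adjusted p = 0.0539), without IkL/L replicate 2 in all conditions (0.051) or on the mean of its probe sets. The Lif, App and Cd9 calls held under every setting. Lif is among the 100 measured genes nearest Ikzf1.

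Camera called the BCR signalling list lower in IkL/L in each condition, though 0 of its 28 genes passed in limma without stimulus or at 12 h. Without stimulus the median was -0.289 (camera adjusted p = 0.000564, 0.339 with an estimated correlation and 0.228 with fry). A few of these components were lower in IkL/L cells at 3 h. Of 28 measured, 5 were lower and 0 higher (10 and 2 adjusted over the list alone), with camera adjusted p = 6.06e-05 and adjusted p = 0.378 with an estimated correlation. Pik3cd, the catalytic p110 delta subunit of PI3 kinase, was 3.68-fold lower (log2 -1.88, SE 0.22, adjusted p = 0.00365), with an adjusted p of 0.0829 without IkL/L replicate 2 in all conditions. Cd79b was 3.48-fold lower (log2 -1.80, adjusted p = 0.00973), but not without WT 3 h replicate 2 (adjusted p = 0.095), IkL/L 3 h replicate 2 (0.0949), WT replicate 1 in all conditions (0.0655) or IkL/L replicate 2 in all conditions (0.0742). Of 23 quiescence genes 5 were lower (10 adjusted over the list alone; camera adjusted p = 1.05e-05, and adjusted p = 0.132 with an estimated correlation). The largest of these falls was in Pik3ip1, an inhibitor of PI3 kinase (4.04-fold, log2 -2.02, SE 0.19, adjusted p = 0.00121), which held under every setting. S1pr1 was 3.4-fold lower (log2 -1.77), with adjusted p = 0.00199 and 0.0518 without WT replicate 1 in all conditions.

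Of 25 inhibitory regulators 1 was lower at 3 h, Dok3, an adaptor that restrains BCR signalling (log2 -1.61; 7 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000739, and adjusted p = 0.132 with an estimated correlation). Dok3 was not called without WT 3 h replicate 1 (adjusted p = 0.0682), WT 3 h replicate 2 (0.117), IkL/L 3 h replicate 2 (0.161), WT replicate 1 in all conditions (0.0916) or IkL/L replicate 2 in all conditions (0.137). Of 13 MAPK feedback regulators 3 were higher and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.000739, and adjusted p = 0.18 with an estimated correlation). At 3 h 310 genes differed, 152 higher and 158 lower, and 572 with the shared replicate term. The count was 203 without either unstimulated WT replicate, 134 without WT 3 h replicate 1, 40 without WT 3 h replicate 2, 166 without IkL/L 3 h replicate 1 and 33 without IkL/L 3 h replicate 2. It was 109 without WT replicate 1 and 40 without IkL/L replicate 2 in all conditions. Under housekeeping scaling 141 were higher and 94 lower.

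At 12 h Nrp1 was 10.1-fold higher in IkL/L than in WT cells (log2 3.33, SE 0.47, adjusted p = 0.0146), a call lost without IkL/L 12 h replicate 2 (adjusted p = 0.146), without WT replicate 1 in all conditions (0.0966) and without IkL/L replicate 2 in all conditions (0.197). Ccl22, which attracts cells bearing the receptor CCR4, was at least 5.56-fold higher (log2 2.90, SE 0.15, adjusted p = 4.18e-05), and Axl at least 6.7-fold higher (log2 2.78, SE 0.16, adjusted p = 4.18e-05). Both held under every setting. Ms4a6c was 5.58-fold lower (log2 -2.48, SE 0.28, adjusted p = 0.00583), with an adjusted p of 0.109 without IkL/L replicate 2 in all conditions, and it was also not called on the mean of its probe sets. Nrp1 and Ms4a6c were not called when only the 4 arrays compared were fitted.

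Plasma cell and unfolded protein response genes were shifted up as a list in IkL/L at 12 h, though only 2 of 19 were higher, Ell2 and Manf (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.65e-05, and adjusted p = 0.0999 with an estimated correlation). Ell2 (log2 1.58) was not called without WT 12 h replicate 2 (adjusted p = 0.171), IkL/L 12 h replicate 2 (0.239) or IkL/L replicate 2 in all conditions (0.496). Manf (log2 0.73) was not called without WT 12 h replicate 2 (0.171), IkL/L 12 h replicate 1 (0.0797), IkL/L 12 h replicate 2 (0.107), WT replicate 1 in all conditions (0.103), IkL/L replicate 2 in all conditions (0.211) or under housekeeping scaling. Ell2 was also not called on the mean of its probe sets, and neither gene was called when only the 4 arrays compared were fitted. J chain transcripts, which plasma cells make in quantity, differed between sources: Jchain read 4.28 and 6.90 in the IkL/L 12 h replicates and 3.84 and 3.58 in the WT 12 h replicates. Glycolysis genes, with 0 of 17 past the threshold in limma (0 adjusted over the list alone), had a camera adjusted p of 0.00252, and adjusted p = 0.143 with an estimated correlation and 0.00749 with fry. At 12 h camera also called BCR signalling components (median -0.243, adjusted p = 9.69e-05), quiescence genes (-0.305, 0.00212) and inhibitory regulators (-0.163, 0.0206) lower in IkL/L. It called ribosome biogenesis (0.165, 0.000809), cholesterol synthesis (0.355, 0.000906) and interferon genes (0.518, 0.0206) higher. Of their genes only Lax1 passed in limma. None of these calls held with an estimated correlation (adjusted p from 0.213) or with fry (from 0.0899).

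At 12 h 112 genes differed, 82 higher and 30 lower, and 187 with the shared replicate term. The count was 72 without either unstimulated WT replicate, 71 without either 3 h WT replicate, 34 without WT 12 h replicate 2, 72 without either 3 h IkL/L replicate and 24 without IkL/L 12 h replicate 2. It was 78 without WT replicate 1 and 4 without IkL/L replicate 2 in all conditions. Unadjusted p values under 0.05 in limma numbered 1817, against 1963 without stimulus and 2314 at 3 h. With no difference at all, a share of 0.05 of the 18193 genes would fall there in each condition.

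**Figure D4:**
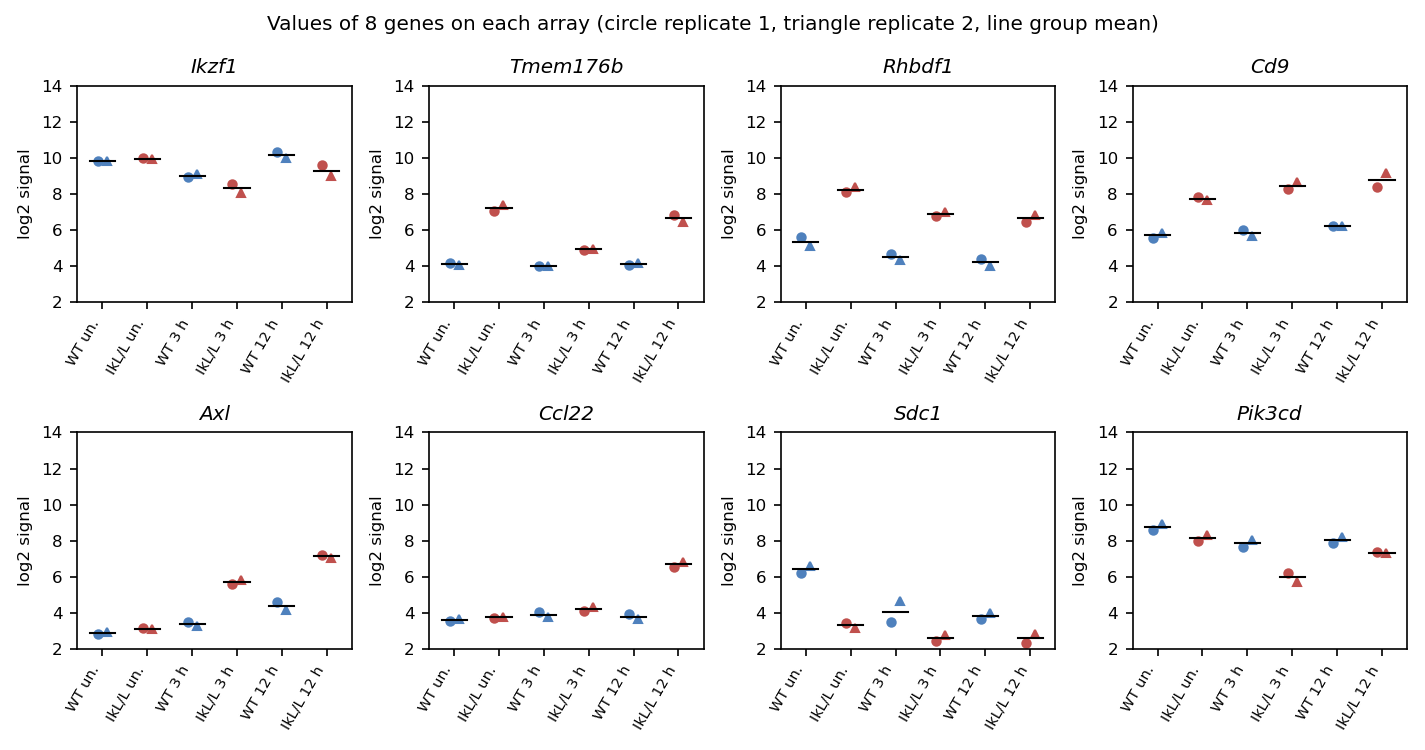
Log2 signal of 8 genes (vertical axes) in the 6 groups (horizontal axes; WT blue, IkL/L red), with circles for replicate 1, triangles for replicate 2 and lines for the mean of 2. Tmem176b, Rhbdf1 and Cd9 are higher in IkL/L in each condition, Axl parts from 3 h on (at least 2.81-fold, then at least 6.7-fold at 12 h), Ccl22 parts at 12 h (at least 5.56-fold), and Ikzf1 spans 8.08 to 10.33.

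Averaged over the 3 conditions, Rhbdf1 was at least 5.86-fold higher in IkL/L (log2 2.58, SE 0.13, adjusted p = 1.46e-05), Cd9 5.28-fold (log2 2.40, SE 0.14, adjusted p = 2.51e-05) and App at least 3.54-fold (log2 2.35, SE 0.14). Unc5cl was at least 2.29-fold lower (log2 -2.04, SE 0.16, adjusted p = 0.000199) and Ms4a6c 3.93-fold lower (log2 -1.97, SE 0.16), the latter not on the mean of its probe sets. Bcl2l2 was at least 2.53-fold higher (log2 1.39, SE 0.077, adjusted p = 2.51e-05). Of 28 BCR signalling components 10 were lower and 1 higher (15 and 2 adjusted over the list alone), led by Syk (log2 -1.09) and Pik3cd (log2 -1.06), with camera adjusted p = 3.05e-07 and adjusted p = 0.196 with an estimated correlation. Syk was not called without IkL/L replicate 2 in all conditions. Of 25 inhibitory regulators 7 were lower and 1 higher (11 and 2 adjusted over the list alone; camera adjusted p = 3.08e-05, and adjusted p = 0.0647 with an estimated correlation), led by Dok3 (log2 -1.19). Of 23 quiescence genes 10 were lower (14 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.2e-07, and adjusted p = 0.0748 with an estimated correlation).

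In limma 1107 genes differed on this average, 621 higher and 486 lower. The count was 1763 with the shared replicate term, 629 without WT unstimulated replicate 2, 698 without WT 3 h replicate 2, 610 without IkL/L 3 h replicate 2 and 653 without IkL/L 12 h replicate 2. Without WT replicate 1 in all conditions the count was 943, and without IkL/L replicate 2 in all conditions it was 227. Ikzf3, Myc, Egr1, Cd69, Cd86, Ccnd2, Cdkn1b, Fcgr2b and Cd22 were not past the threshold between genotypes in any condition or on average. The nearest of these was Cd22 on average (log2 -0.52, adjusted p = 0.0674). Ikzf1 came nearer on average without passing (log2 -0.48, adjusted p = 0.0533). Arrays of a genotype with the same replicate number resemble each other, so the average rests on 4 sources of cells rather than 12 independent samples. With 1 mean per source, 2 against 2, 5 genes passed, all higher in IkL/L: Tmem176b, Cd9, Axl, Bcl2l2 and Ifitm2, of which Ifitm2 was chosen after its value was seen. Rhbdf1, App, Unc5cl, Ms4a6c, Syk, Pik3cd and Dok3 did not pass in that fit. Of the genes called without stimulus, 41 higher and 23 lower were called in the same direction at 3 h, and 31 higher and 10 lower at 12 h. The same 4 sources supply every condition, so differences between sources alone would also recur, and no chance level is given.

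The design also asks whether the response to anti-IgM itself differed between genotypes. At 12 h the fitted IkL/L minus WT response was higher for Ccl22 (log2 2.74, SE 0.22, adjusted p = 0.00326) and for Axl (log2 2.52, SE 0.22, adjusted p = 0.00429). Ccl22 lay between 3.57 and 3.89 in all WT groups and at 3.73 in unstimulated IkL/L cells, and unstimulated Axl at 2.85 in WT and 3.11 in IkL/L. These levels are under the floor, so no fold is given for the difference. At 3 h the response of Axl was also higher in IkL/L (log2 2.07, SE 0.22, adjusted p = 0.0263), while Tmem176b was lower in its response (log2 -2.17, SE 0.22, adjusted p = 0.0263): its signal fell in stimulated IkL/L cells and lay near 4 in all WT cells. In limma 7 genes passed at 3 h, 5 higher and 2 lower, and 4 passed at 12 h, all higher. Unadjusted p values under 0.05 in limma numbered 1027 and 1126 of 18193 genes, where a share of 0.05 would fall there with no difference. Without WT replicate 1 in all conditions, or without IkL/L replicate 2 in all conditions, 0 genes passed in limma at either time. A block for replicate within genotype gave 27 genes at 3 h and 26 at 12 h, which included all 7 and all 4, and the replicate term shared by both genotypes gave 11 and 19.

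Most of these interaction calls were lost when some single array was left out. Calls at 3 h were also lost without 12 h arrays, which do not enter that comparison. Each such fit has fewer residual degrees of freedom than the full one, so a lost call does not by itself point to the values of that array. Ccl22 kept its call without any single array, but not without WT replicate 1 (adjusted p = 0.0597) or IkL/L replicate 2 (0.214) in all conditions. Axl at 12 h lost its call without WT unstimulated replicate 2 (adjusted p = 0.0523) and without those 2 sets of arrays (0.0521 and 0.292). At 3 h 0 genes passed in limma without either unstimulated WT replicate or without any of the 4 arrays at 3 h, 1 without either unstimulated or either 12 h IkL/L replicate, and 2 without either 12 h WT replicate. At 12 h the count was 2 without WT unstimulated replicate 1, 1 without WT unstimulated replicate 2, 2 without WT 12 h replicate 2, 2 without any of the 4 arrays at 3 h, and 7 without IkL/L unstimulated or 12 h replicate 1. For Axl at 3 h the adjusted p was between 0.0644 and 0.264 without any 1 of the 4 unstimulated or 4 3 h arrays and 0.0668 without either 12 h IkL/L replicate. For Tmem176b it was 0.0909 without WT unstimulated replicate 1, 0.264 without WT unstimulated replicate 2, 0.0809 without IkL/L unstimulated replicate 2, and between 0.0892 and 0.244 without any 1 of the 4 arrays at 3 h. Cholesterol synthesis rose more in IkL/L at 12 h as a list (median log2 difference 0.46, with 0 of 16 genes past the threshold in limma and 1 adjusted over the list alone), with camera adjusted p = 0.000272, adjusted p = 0.387 with an estimated correlation and 0.429 with fry.

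Camera also called 6 other list differences between the responses. Each had 0 genes past the threshold in limma. All 6 calls were lost with an estimated correlation and with fry. At 12 h the response of NF-kB targets was lower in IkL/L (median -0.49, 0 of 19 adjusted over the list alone; camera adjusted p = 0.000585, adjusted p = 0.627 with an estimated correlation and 0.429 with fry). Immediate early genes were lower (median -0.364, 5 of 24 adjusted over the list alone; camera adjusted p = 0.00477, adjusted p = 0.627 with an estimated correlation and 0.539 with fry). These calls were lost without IkL/L unstimulated replicate 2 (adjusted p = 0.353 and 0.419) and without IkL/L replicate 2 in all conditions (0.358 and 0.122). Plasma cell and unfolded protein response genes were higher (median 0.356, 0 of 19 adjusted over the list alone; camera adjusted p = 0.00639, adjusted p = 0.387 with an estimated correlation and 0.429 with fry). They were not called without IkL/L unstimulated replicate 1 (0.221) or 12 h replicate 1 (0.0603). Interferon genes, which differ between the WT replicates, were higher (median 1.055, 0 of 19 adjusted over the list alone; camera adjusted p = 0.00639, adjusted p = 0.738 with an estimated correlation and 0.794 with fry). They were not called without WT unstimulated replicate 1 (0.889), WT 12 h replicate 2 (0.618), IkL/L unstimulated replicate 1 (0.224) or IkL/L 12 h replicate 1 (0.0603). At 3 h NF-kB targets were lower (median -0.347, 0 of 19 adjusted over the list alone; camera adjusted p = 0.0113, adjusted p = 0.963 with an estimated correlation and 0.752 with fry). They were not called without IkL/L unstimulated replicate 2 (0.798), IkL/L 3 h replicate 1 (0.212), WT 3 h replicate 2 (0.0745) or IkL/L replicate 2 in all conditions (0.439). MAPK feedback regulators were higher at 3 h (median 0.161, 2 of 13 adjusted over the list alone; camera adjusted p = 0.0223, adjusted p = 0.963 with an estimated correlation and 0.652 with fry). That call was lost with the shared replicate term (0.0521), without WT replicate 1 (0.117) or IkL/L replicate 2 (0.122) in all conditions, and without any of 5 single arrays (adjusted p between 0.0757 and 0.139).

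Some transcripts differed between the sources of the cells within a genotype, and some of these also differed between conditions. Apart from the interferon and sex-linked lists they were chosen after their values were seen. The 3 WT replicate 1 arrays had Xist, the transcript of the inactive X chromosome, between 10.01 and 10.69 and the Y-linked Eif2s3y between 2.41 and 2.83, a female pattern, while the other 9 arrays had a male one. Type I interferon genes were higher in WT replicate 1 than in WT replicate 2 by a median of 2.07 on the log2 scale, for 19 of 19 genes in all 3 conditions. In IkL/L cells the same difference was -0.185, and the IkL/L mean lay between the WT replicates, 0.96 below replicate 1 and 1.39 above replicate 2. In each condition IkL/L replicate 2 had the most Jchain (8.68 without stimulus) and the most of the heat shock transcript Hspa1a (8.23 without stimulus, 8.78 at 3 h and 7.21 at 12 h). Both also differed between conditions. Hspa1a read 6.99 and 7.09 in unstimulated WT cells and 3.5 and 4.37 in WT cells at 12 h. Jchain in WT replicate 2 read 7 without stimulus and 3.58 at 12 h. The neutrophil transcript S100a8 was higher in replicate 2 than in replicate 1 in each of the 6 groups.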

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

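The tests on the resting cells and on the interferon genes were chosen only after the result was seen, while the other splits of the arrays and the region around Ikzf1 were planned before. A difference between the genotypes' responses, tested directly in limma, singled out 7 genes at 3 h: Axl (log2 2.07), the clone-named C730049O14Rik (1.88, chosen after its value was seen), Rflnb (1.76), Fjx1 (1.55), Xcl1 (1.33), Il16 (-1.47) and Tmem176b (-2.17). The same test singled out 4 genes at 12 h: Ccl22 (2.74), Axl (2.52), Rnf125 (2.29) and Tceal8 (1.46). The Rnf125 value follows from the signal floor: unstimulated IkL/L cells were already at 3.14 and 3.83 and had little room to fall, while WT cells fell from 5.94 and 5.88 to 3.21 and 2.99. Rflnb and C730049O14Rik, low in unstimulated IkL/L cells, and Tmem176b, low in all WT cells, share this limit. Axl, Ccl22, Fjx1, Tceal8 and Xcl1 were low in unstimulated cells of both genotypes and higher in stimulated IkL/L cells. At 12 h the means of Axl were 4.35 in WT and 7.13 in IkL/L, and those of Ccl22 3.78 and 6.68. For these genes a low start leaves the size of the rise uncertain but does not by itself make the difference. Of all these genes only Il16 was measured above the floor throughout. Probe sets with no single gene name, which the comparisons leave out, also carried signal: of 10092, 872 changed in WT cells at 3 h (304 up and 568 down) and 187 differed between genotypes on average (82 up and 105 down).

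The first pattern weighed is the set of genes that differ between genotypes over the 3 conditions. In an additive model of condition and genotype 1012 genes differed, and of 100 splits of the arrays within conditions 1, the real one, gave as many. The highest other split gave 99 genes and parted replicate 1 from replicate 2; only 3 splits keep the 4 sources whole, too few for a share under 0.05. Genes carried along with the targeted locus were tested by place: of the 100 genes nearest Ikzf1 7% differed against 6.08% elsewhere, a ratio of 1.15 (Fisher p = 0.672). The 7, named after their values were seen, were H2az2, Hus1, Lif, Mtmr3, Pno1, Tns3 and Xbp1, 5 higher and 2 lower in IkL/L. No excess was seen over these 100 genes, but the test cannot exclude a short carried region with few altered genes. Which of the differences come from the mice, the sort, genes carried along with the locus or the genotype itself stays open, as each genotype has 2 sources.

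The second pattern is that unstimulated IkL/L cells lay toward the anti-IgM response. The IkL/L minus WT difference of one unstimulated IkL/L replicate correlated across genes with the 3 h response of the other IkL/L replicate at r = 0.294 and 0.407, no array being shared, against -0.0982 and -0.0981 for the difference between the WT replicates. The lower value, 0.294, came from IkL/L replicate 1, which argues against a single culture (replicate 2) as the whole cause. The shift was small: genes risen in both genotypes at 3 h, by a median of 1.09 in WT, were higher by a median of 0.12 in IkL/L replicate 1 and 0.404 in replicate 2, the one with the most Hspa1a and Jchain, and genes fallen in both differed by -0.227 and -0.173. Unlike the correlations, these medians share the unstimulated arrays with the choice of the risen and fallen genes. Leaving out 97 immediate early and heat shock genes (0.294 and 0.403) moved the correlations too little to decide anything, so a stress response, or a handling or day shared by both IkL/L cultures, stays open beside an effect of genotype.

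The third pattern is the interferon genes, which were higher in WT replicate 1 than in WT replicate 2. The IkL/L mean lay between them, 0.96 below replicate 1 and 1.39 above replicate 2, so a high replicate 1 and a low replicate 2 are both open. An experiment effect shared by arrays of the same number would part the IkL/L replicates in the same direction. There replicate 1 minus replicate 2 had a median of -0.185 over the conditions. Replicate 2 was the higher without stimulus (6.55 against 5.55), but replicate 1 was at 3 h (6.04 against 5.67) and 12 h (5.67 against 5.32). In WT at 3 h the gap was wider (7.18 against 3.50). A shared effect as large as that in WT was not seen, while a smaller one stays open. The sex of the source cannot be told apart from the source itself, since 1 source of 4 has a female pattern. An infection or immune stimulus of a mouse could also move them and was not tested.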

How the results depend on the processing

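With 2 arrays per group and medians near the signal floor, counts of genes moved when single arrays were left out. Leaving out arrays also lowers the residual degrees of freedom, and the cause of a moved count was not tested. With each array left out in turn, counts ranged from 2427 to 3625 for WT at 3 h, 2237 to 3545 for WT at 12 h, 2547 to 3800 for IkL/L at 3 h, 1905 to 3325 for IkL/L at 12 h, 1055 to 2082 and 1629 to 2974 for 12 h against 3 h in WT and IkL/L, 33 to 204, 33 to 327 and 24 to 162 for genotype without stimulus, at 3 h and at 12 h, 610 to 1167 on average, and 0 to 2 and 1 to 7 for the difference between responses at 3 h and 12 h. The correlations of responses ranged from 0.850 to 0.893 at 3 h and from 0.787 to 0.865 at 12 h.

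With a replicate block shared by both genotypes the counts were 400, 572 and 187 for genotype in the 3 conditions, 1763 on average and 11 and 19 for the difference between responses. The replicate block within genotype gave 3090 for WT at 12 h against 3 h and 27 and 26 for the difference between responses. It called Lat2 in the difference at 12 h (adjusted p = 0.0167). It also called Ccnd2 (0.917) and Cd69 (-0.807) in WT at 12 h, Egr1 (1.07) in IkL/L at 3 h, and Myc (0.598), Cd22 (-0.635), Ikzf1 (-0.686) and Cd69 (-0.694) in IkL/L at 12 h, none of them past the threshold without it. It ended the call of Ccna2 in IkL/L at 12 h. Among the genes that it added to the difference at 3 h were Lif (2.90, adjusted p = 0.0061 against 0.185 without it), Pdcd1 (1.91, 0.0278 against 0.185), Bmf (-1.35, 0.023 against 0.427), Cd79b (-1.52, 0.0304 against 0.427) and Pik3ip1 (-1.65, 0.0216 against 0.136). At 12 h they included Nrp1 (2.78, 0.0319 against 0.431), Sspn (2.70, 0.0319 against 0.568), Fabp5 (-1.77, 0.00881 against 0.224) and Nr4a2 (-1.89, 0.0496 against 0.505). Camera with that block also called myeloid markers in the difference at 12 h (adjusted p = 0.0191, and adjusted p = 0.378 with an estimated correlation in the blocked fit).

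Taking the mean of probe sets gave 2 and 13 genes for the difference between responses at 3 h and 12 h, and removing the dimmest 1 in 3 genes gave 2 at 3 h. An intensity trend gave 7 at 12 h. Testing every probe set on its own, with more tests, gave 5648 and 5430 in WT and 6150 and 5062 in IkL/L at 3 h and 12 h, 4630 for IkL/L at 12 h against 3 h and 0 for the difference at 3 h. Only the arrays compared, with fewer degrees of freedom, gave 1197 for WT at 12 h against 3 h, 44, 128 and 4 for genotype in the 3 conditions and 2 and 2 for the difference between responses. Housekeeping scaling gave 9961 for IkL/L at 12 h, 69 for genotype at 12 h and 2 and 2 for the difference between responses. Under it Ccna2 in IkL/L at 12 h turned from 0.36 (adjusted p = 0.0496) to -0.069 (adjusted p = 0.616).

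With the source as a random block (correlation 0.166) 695 genes differed between genotypes on average and 14 in the response at 12 h, and 1 mean per source gave 5 on average. Without WT replicate 1 in all conditions the counts were 1771 and 1639 for WT at 3 h and 12 h, 524 for WT at 12 h against 3 h, 83 and 109 for genotype without stimulus and at 3 h, and 0 and 0 for the difference between responses. Without IkL/L replicate 2 in all conditions they were 2171 and 1381 for IkL/L at 3 h and 12 h, 1058 for IkL/L at 12 h against 3 h, 16, 40 and 4 for genotype in the 3 conditions, 227 on average, and 0 and 0 for the difference between responses. The correlation of responses at 3 h was 0.904 without those dimmest genes, 0.846 from replicate 1 alone and 0.839 from replicate 2 alone, and at 12 h it was 0.741 from replicate 2 alone. Array weights were identical within groups. Most of the genes named for a genotype difference lost their call under some setting, fits without single arrays among them. In the counts that follow, a gene or list uncalled in both fits also counts as the same, so they do not measure how often calls held. Of the other values under settings fixed in advance 20009 stayed the same, 1144 were weaker, 152 stronger and 29 moved; of those added after the data were seen 3505 stayed the same, 460 were weaker, 31 stronger and 11 moved.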

Other observations

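Other gene lists held members that changed without a camera call for the list. In WT cells at 3 h, camera called none of these: G2/M and mitosis (1 higher and 2 lower of 23, adjusted p = 0.154), the BCL2 family (2 and 5 of 13, 0.716), germinal centre markers (2 and 1 of 12, 0.904), marginal zone markers (4 and 4 of 15, 0.913), transitional and immature markers (2 and 4 of 14, 0.143), B-1 markers (1 and 3 of 12, 0.199), Notch-associated genes (3 and 2 of 13, 0.396), the Ikaros family (0 and 2 of 5, 0.158), chemokines and cytokines (4 and 3 of 17, 0.798) and housekeeping genes (2 and 1 of 11, 0.515). Between genotypes on average, camera called transitional and immature markers lower in IkL/L (0 higher and 2 lower of 14, adjusted p = 0.00417, and adjusted p = 0.282 with an estimated correlation), and 0.0721 without IkL/L replicate 2 in all conditions.

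The list medians of markers of other cell types were near the floor on all arrays, between 2.83 and 3.48, but single genes were not. In unstimulated WT cells Cd2 of the T cell list read 9.64 and 9.69 and Itgb3 of the platelet list 8.20 and 7.49, and the neutrophil transcripts S100a8 and Ngp reached 7.26 and 7.38 on single arrays, these neutrophil transcripts being chosen after their values were seen. Cd3e (2.89 and 3.07) and Cd3d (3.27 and 3.33) of the T cell list and Pf4 (3.05 and 2.68) of the platelet list, chosen in the same way, lay near the floor in unstimulated WT cells. In WT cells at 3 h camera called none of these lists: T cell (0 higher and 1 lower of 15, adjusted p = 0.79), myeloid (0 and 0 of 18, 0.913), dendritic cell (0 and 0 of 9, 0.347), NK cell (0 and 0 of 10, 0.925), erythroid (0 and 0 of 8, 0.79) and platelet markers (0 and 1 of 8, 0.879). The sex-linked list held 4 measured genes, too few for the list test, and its levels are given per source in the report.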
